A study of Homo sapiens with 24 samples.

How the data were processed

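PC9 and PC9-OR cells were profiled by chromatin immunoprecipitation and sequencing with a MYC-tag antibody, with 12 immunoprecipitated and 12 input libraries in 12 groups of 2. Per the labels' protocols, 20 ug of sheared chromatin entered each immunoprecipitation, 2.5 ng of the product entered library preparation, and 20M paired-end reads were sequenced per library. The labels' protocols speak of biological replicates. Groups were taken from the sample titles. Per the submitters' processing notes the tools were Trimmomatic, FastQC, Bowtie2 2.4.2, SAMtools 1.16, MACS2 2.2.7.1, deepTools 3.5.1 and bedtools 2.30, with build GRCh37. Their roles, settings and the control used in peak calling are not given in the sources used here.

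The 6 deposited peak lists, 1 per immunoprecipitated group, are in the narrowPeak layout. Each peak has a start and end in bp, a deposited score, the deposited fold enrichment at the summit as a ratio to local background, and the deposited −log10 p and −log10 q, all values of the authors' peak caller, used only to describe, rank or filter within a list. All 6236 peaks had a q of at most 0.05. Peak numbers restart or the peak name changes inside 4 of the lists, so the lists hold 10 peak-calling runs placed one after another. There are 2 runs in 4 lists and 1 run in 2 lists, those of PC9 with METTL7A and of K86A. Whether the other replicate of these 2 gave no peak or was left out is not given. That a run stands for a replicate is an inference. Empty-vector and K86A names carry replicate numbers, and for the other lists which run belongs to which replicate is not given in the sources used here, so runs are called first and second by their place in the list. Coordinates are printed 1-based. Read totals per library were not used here.

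The number of fragments at each summit and the local background were recovered from the deposited fold and p-value. MACS2 computes the fold as (fragments + 1) / (background + 1) and the p-value from the Poisson upper tail, so a whole fragment number fits both only at particular values. A solution was accepted within 1 unit of the tolerance propagated from the deposited rounding. All 6236 peaks were recovered, with a largest misfit of 0.518 units, and 2 had another admissible solution. On simulated data 500 of 500 true pairs were recovered with the right number and 0 of 500 decoys were accepted. The most common background of a run with at least 5 peaks is called its floor and serves as a relative measure of its usable depth. It was 0.0131 and 0.211 in the parental wild-type runs, 0.151 in PC9 with METTL7A, 0.0167 in the first PC9-OR wild-type run, 0.170 in the first empty-vector run, and 0.676 and 0.341 in the PC9-OR METTL7A runs. Recovery, floors, bands and runs were not planned before the data were examined.

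Before the data were examined, the groups, tests, named-peak rule and 15 gene lists were fixed. Lists were compared by 1 bp of overlap, with the smaller list placed at random 1000 times within its chromosomes outside centromere bands, a one-sided permutation p whose smallest value is 0.001, and Benjamini-Hochberg adjustment over 15 pairs of lists. On simulated lists of 83 and 4935 peaks, 1 of 50 tests with 0 planted shared peaks and 50 of 50 with 12 planted shared peaks passed 0.05. Lists of at least 20 peaks were tested for chromosome spread, by a chi-square statistic against 100000 multinomial draws, and for their most filled 1 Mb window. Folds of shared and unshared peaks were compared by a permutation test with 100000 resamples where at least 5 peaks were shared. The share inside or within 1 Mb of a centromere band was tested for every list. Random positions could not fall inside a band, so the random shares are too low. An assembly gap table was not used here. Cytogenetic bands of GRCh37 came from the circlize package. Gene-to-band assignments for the receptor and oncogene list came from textbook knowledge, and they and their comparison with 10000 random sets of bands were chosen after the peaks had been seen. ALK was left out of that table, and some other members of the list are not reported here and did not enter that comparison.

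Named peaks are all peaks of lists with at most 10 peaks, the 10 highest folds of longer lists outside the centromere margin, the 25 highest folds of the PC9-OR METTL7A list absent from the other PC9-OR lists, and positions in 3 or more lists, with METTL7A, EGFR, MET and MYC always reported. Ties at the end of the 25 were broken by chromosome name and start. Only the leading ones are printed. The gene table used here is on another assembly, GRCh38.p14, and gives no positions for GRCh37, so the promoter share, the gene lists by promoter peak and the sequence of peaks were not analysed. Alternatives covered a −log10 q of at least 5, merging within 1 kb and 10 kb, centromere margins of 1 Mb and 100 kb, 50% overlap, widening by 1 kb, whole-genome placement, 5 Mb windows and leaving out each run. Added after the data were seen were a minimum of 5 fragments, placement within 1 Mb, comparison of runs, also with peaks widened by 1 kb, an exact permutation test of log2 peaks per run, and a fold minimum per run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.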

Results

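The series profiled chromatin with an antibody against the MYC epitope tag in PC9 cells, a human lung adenocarcinoma line that depends on mutant EGFR, and in PC9-OR, the osimertinib-resistant line kept in 1 uM osimertinib, an EGFR kinase inhibitor. The tagged protein was METTL7A, a methyltransferase-like protein known from lipid droplets and the endoplasmic reticulum, carrying MYC-tag and FLAG. The 24 libraries fall into 12 groups of 2, of which 6 groups are MYC-tag immunoprecipitations and 6 are matched inputs. PC9 was profiled as wild type and with METTL7A. PC9-OR was profiled as wild type, with an empty vector, with METTL7A, and with the METTL7A form the labels call K86A. The wild-type and empty-vector cells express no tagged METTL7A and give the background of the antibody and of the cells. Whether endogenous c-MYC adds to the peaks of any group was not tested, as the sequence of peaks was not analysed. For each immunoprecipitation group 1 peak list was analysed, so a count of a list has no replicate error of its own, and the spread between the peak-calling runs inside a list is given where it holds 2.

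In PC9-OR cells the METTL7A list held 4937 peaks covering 2410142 bp. The wild-type list held 10 peaks, the empty-vector list 6 and the K86A list 1. The K86A list holds 1 peak-calling run, named as replicate 2, and the other PC9-OR lists hold 2. The METTL7A list was thus 494 times as long as the wild-type list and 823 times as long as the empty-vector list. Of its peaks, 4935 overlapped no peak of these 3 PC9-OR lists, called controls below although K86A is a METTL7A form. Lists of 10, 6 and 1 peaks can overlap few others. This number therefore follows from list length and does not show sites particular to METTL7A. The exact 95% Poisson intervals, which cover counting error only, were 4800 to 5077 for METTL7A, 4.80 to 18.4 for wild type and 2.202 to 13.06 for the empty vector.

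The METTL7A list is made of 2 peak-calling runs, and nearly all of its peaks came from the second, with 4870 peaks, or 98.6%. The first run held 67. At a minimum overlap of 1 bp, 2 of the 66 first-run peaks on standard chromosomes lay on a second-run peak, 3.03% with an exact 95% interval of 0.369 to 10.5%. Random placement along the chromosomes gave a mean of 0.193, with a permutation p of 0.013 and 0.083 after adjustment over 45 pairs of runs. Placement within 1 Mb of each peak gave a mean of 1.43 and a permutation p of 0.43. With peaks also widened by 1 kb, 10 were shared against a mean of 4.37, with a permutation p of 0.007 and 0.052 after adjustment. Sharing beyond local crowding thus did not pass 0.05 after adjustment under either overlap rule. With runs taken as replicates, an inference, METTL7A exceeded wild type by 7.57 on the log2 scale of peaks per run (SD 4.37 and 2.24, n = 2 runs each), with a two-sided exact permutation p of 0.33, the smallest this design allows. Against the 4 wild-type and empty-vector runs together the difference was 7.78, with a two-sided exact permutation p of 0.13, also the smallest possible.

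**Figure D1:**
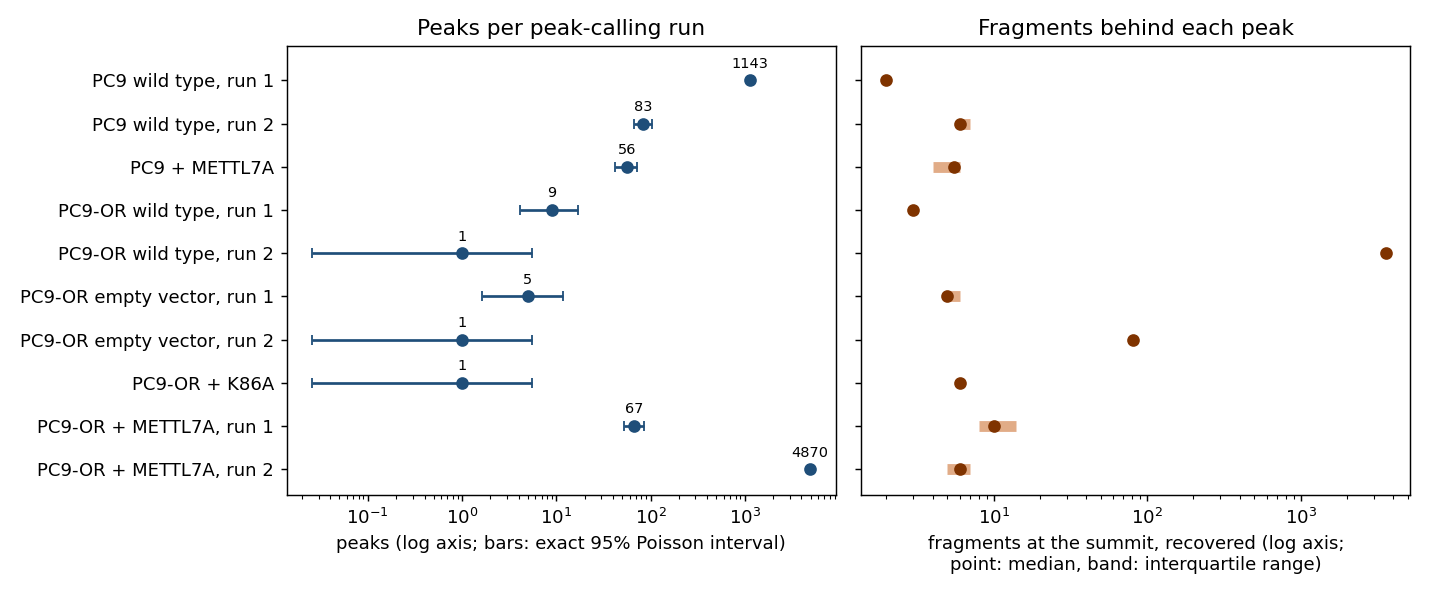
The left panel gives the number of peaks in each of the 10 peak-calling runs on a log axis with exact 95% Poisson intervals. The right panel gives the recovered number of fragments at the peak summits, with the median as a point and the interquartile range as a band. The run with 4870 peaks stands apart from the 67 peaks of the other METTL7A run of PC9-OR, and the 1143 peaks of the first parental wild-type run have a median of 2 fragments.

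Peaks of the PC9-OR METTL7A list crowded in a few chromosome arms. Chromosome 20 held 576 second-run peaks, 5.81 times the number its length gives, chromosome 22 held 336, 4.16 times, and chromosome 16 held 326, 2.29 times. Chromosome 4 held 69, or 0.229 times, and chromosome 13 held 45, or 0.248 times. The first run also had its largest excess on chromosome 20, with 12 peaks, 8.93 times the number by length. The pattern was not limited to METTL7A cells. The second parental wild-type run held 4 peaks on chromosome 20, 2.37 times the number by length, 5 on 22, 3.63 times, and 6 on 16, 2.48 times. On chromosomes 4 and 13 it was at 0.39 and 0.324 times. The first parental wild-type run was at 1.33 times on chromosome 20, 0.633 on 22 and 0.989 on 16. The chi-square statistic of the whole list against chromosome length was 4488, with a multinomial simulation p of 1e-05, the smallest the 100000 draws can give. With peaks within 10 kb merged the statistic was 1672, with the same p. The draws treat neighbouring peaks as independent and use the full length of each chromosome, gaps included. This p therefore does not measure a spread over independent sites.

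The most filled 1 Mb window was chromosome 20 from 58000001 to 59000000 (GRCh37), at the border of 20q13.32 and 20q13.33, with 151 peaks. The highest count in any of 1000 random placements was 24, which gives a permutation p of 0.001, the smallest possible. This window was also the most filled in each run alone, with 144 second-run and 7 first-run peaks. With peaks within 10 kb merged, the fullest window was instead chromosome 5 from 1 to 1000000, with 28, so rank and size rest on counting neighbouring peaks singly. By band, 20q13.32 held 90.5 second-run peaks per Mb and 20q13.33 held 56.9. They were followed by 7p22.3 with 43.9, 5p15.33 with 40.4, 22q11.22 with 30.0, 22q11.21 with 29.8, 16q24.2 with 29.38, 22q11.23 with 29.17 and 3p25.3 with 29.0, against a genome mean of 1.57 per Mb. The first run held 5 peaks each in 20q13.32 and 20q13.33 and 1 each in 22q11.22, 22q11.23 and 3p25.3. It held 0 in 7p22.3, 5p15.33, 22q11.21 and 16q24.2. Of these bands, the second parental wild-type run held 4 peaks in 5p15.33, 3 in 20q13.33, 1 each in 7p22.3 and 22q11.23, and 0 in the others. The median recovered local background of the second-run peaks was uneven within these regions, at 7.65 times the floor of that run in 20q13.32 but 1.57 times in 20q13.33, and at 6.15 times in 3p25.2 but 2.39 times in 3p25.3. In 7p22.3 and 5p15.33 it was 1.09 times, and in 22q11.22 and 16q24.2 it was at the floor.

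**Figure D2:**
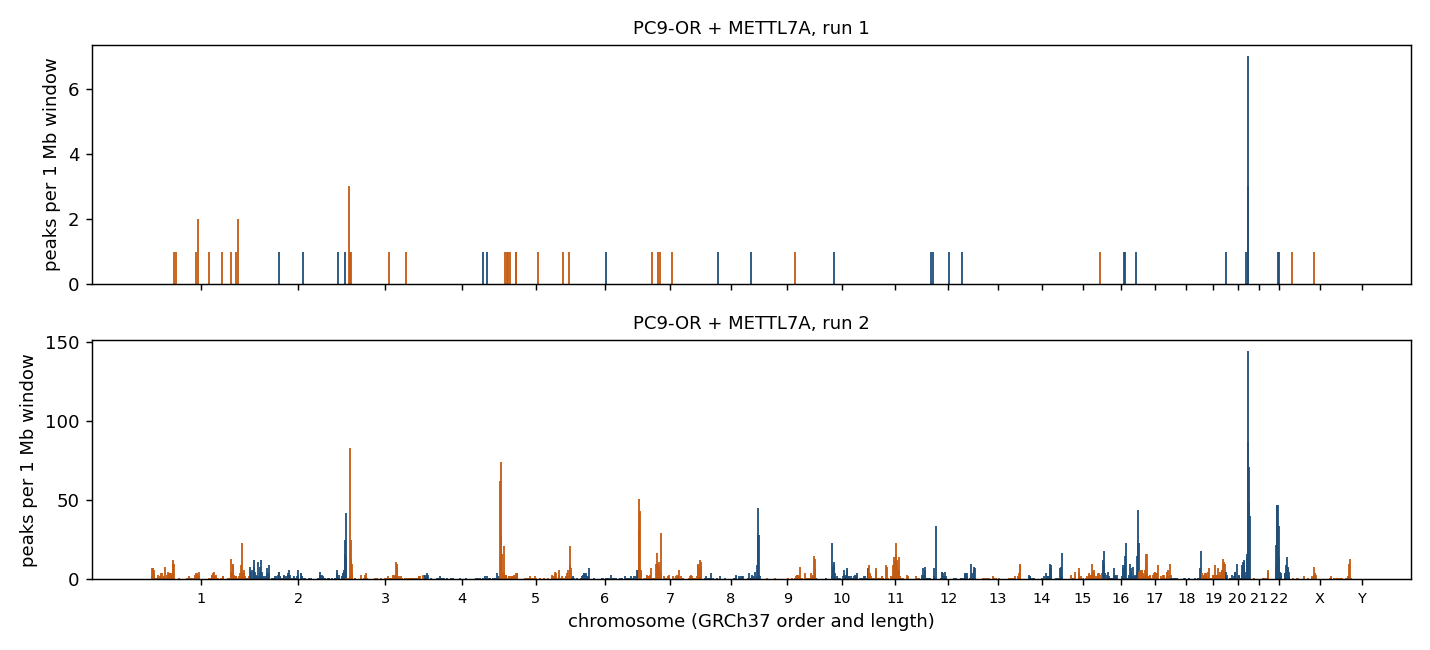
Peaks per 1 Mb window along the chromosomes are drawn for the first run (top) and second run (bottom) of the PC9-OR METTL7A list, with colours alternating by chromosome and separate vertical scales. The highest bar lies on chromosome 20 in both, at 7 and 144 peaks.

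Among the 25 peaks with the highest deposited fold enrichment that were absent from the PC9-OR controls, 9 lay on chromosome 20 and 5 on chromosome 5, and all came from the second run. The highest was 20:58325087-58327775 in 20q13.32, with a fold of 18.9, a −log10 q of 45.6 and 46 recovered fragments. A neighbour at 20:58317075-58320260 had a fold of 13.32 and 48 fragments. Outside chromosome 20 the leading peaks were 5:769860-771899 in 5p15.33, with a fold of 11.9, 3:12951830-12953853 in 3p25.2, with 10.9, and 8:86556362-86556915 in 8q21.2, with 10.4. The others include 3p25.3 at 9.74, 7p15.3 at 9.70 and 22q11.23 at 9.70. Peaks are given by band because a gene annotation of GRCh37 was not used here, so no exon, intron or promoter is assigned.

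**Figure D3:**
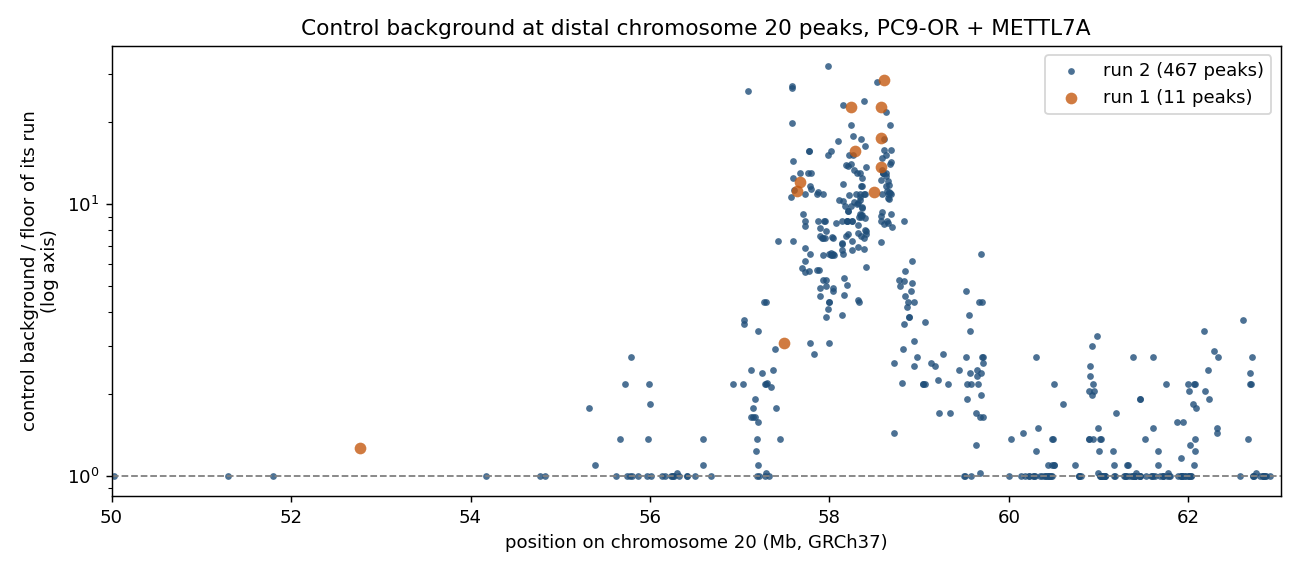
Each point is a peak of the PC9-OR METTL7A list on distal chromosome 20, by position in Mb (GRCh37) and by recovered local background over the floor of its run, on a log axis, with the floor as a dashed line at 1. In the window from 58 to 59 Mb the median is 17.6 times the floor in the first run and 9.05 times in the second.

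The series title concerns oncogene amplification, and the bands of 36 genes of the receptor and oncogene list were therefore compared. They occupy 34 bands, of which 13 exceeded the genome mean density in the second run, as did 206 of all 862 bands. The band of TERT, the catalytic subunit of telomerase, held 182 peaks, 25.7 times the genome mean per Mb. The band of CRKL, an adaptor protein of receptor signalling, was at 18.9 times and that of CCND1 (cyclin D1) at 12.7. The EGFR band 7p11.2 was at 5.25 times with 33 peaks, the METTL7A band 12q13.12 at 2.65 and the MYC band 8q24.21 at 0.757. The MET band 7q31.2 held 0 peaks, as did those of ROS1, NKX2-1 and MDM2. All of these are second-run values, and the first run held 0 peaks in the TERT, CRKL, CCND1 and EGFR bands and 1 in that of MDM2. Of its 83 peaks, the second parental wild-type run held 4 in the TERT band, 2 in the EGFR band, 1 in the CCND1 band and 0 in the CRKL band. Peaks in these bands are thus not shown to be particular to METTL7A cells. The median over the 34 bands was 1.15 peaks per Mb, against 0.385 for random sets of bands and 0.45 for sets matched on band stain. No p-value is attached, because the bands were assigned after the peaks had been seen and some list members were left out. A band spans several Mb and many genes, so these values describe regions and not the genes.

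**Figure D4:**
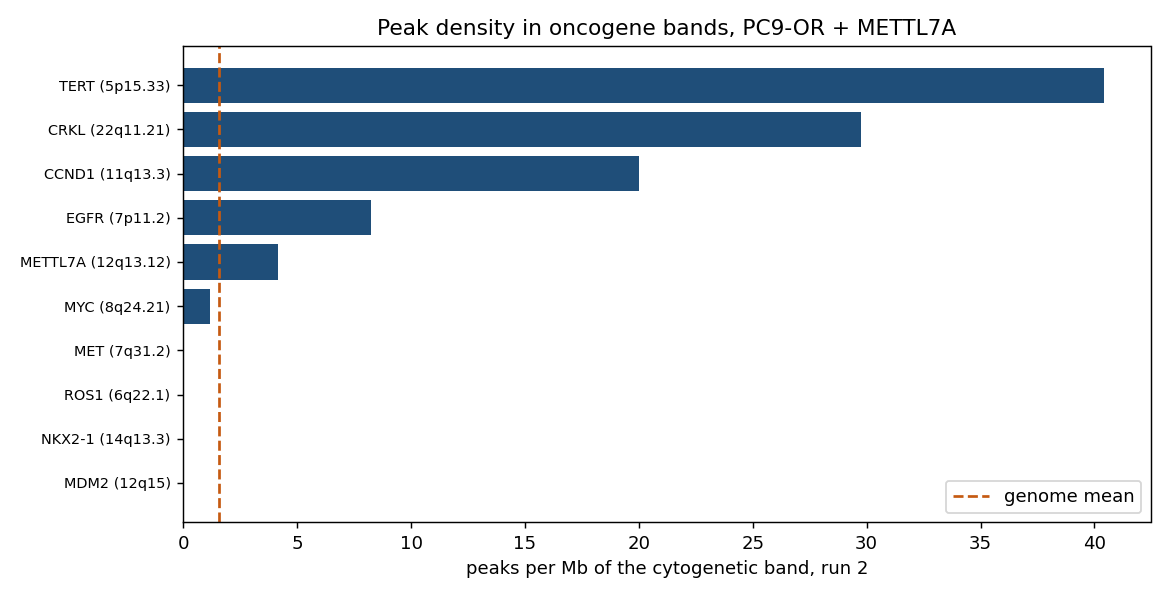
Bars give second-run peaks of the PC9-OR METTL7A list per Mb for the cytogenetic bands that hold METTL7A and the receptor and oncogene list members named in the text, and the dashed line is the genome mean of 1.57 per Mb. TERT leads at 40.4 per Mb and EGFR stands at 8.25.

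In parental PC9 cells the numbers ran the other way. The METTL7A list held 56 peaks (exact 95% Poisson interval 42.3 to 72.7) and the wild-type list 1226 (1158 to 1297), a ratio of 0.0457. This ratio sets 1 METTL7A run against 2 wild-type runs, because the METTL7A list holds 1 run. Of the wild-type peaks, 1143 came from the first run, where 1054 rested on 2 recovered fragments, and 83 from the second, with a median of 6 fragments. With only peaks of at least 5 fragments the lists held 41 and 83, a ratio of 0.494, and at a −log10 q of at least 5 each held 4. The 2 wild-type runs shared 0 peaks. The leading METTL7A peaks besides 11p15.4 were 12:82183818-82184072 in 12q21.31, with a fold of 7.82, and 5:158646414-158646724 in 5q33.3, with 7.53. The leading second-run wild-type peaks, again besides 11p15.4, were 18:8856982-8857346 in 18p11.22 and 5:34193080-34193481 in 5p13.2, both at 7.43. Neither list was crowded into a 1 Mb window, with permutation p of 0.43 for METTL7A and 0.96 for wild type, although the second wild-type run alone passed, with 3 peaks between 62 and 63 Mb of chromosome 20 and a permutation p of 0.02. Chromosome spread departed from length in the wild-type list, with a chi-square statistic of 100.5 and a multinomial simulation p of 1e-05. It did not pass in the METTL7A list, with 29.1 and 0.17. These draws also use full chromosome lengths and treat peaks as independent.

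Between the lines, METTL7A cells had 88.2 times as many peaks in PC9-OR as in PC9, and wild-type cells had 123 times as many in PC9 as in PC9-OR. Most of the peaks behind each ratio came from 1 run. The first PC9-OR METTL7A run alone gave 1.2 times, 67 against 56. The second parental wild-type run gave 9.22 and 83.0 times the PC9-OR wild-type runs, and at a −log10 q of at least 5 the wild-type lists held 4 and 1. The METTL7A lists of the 2 lines shared 2 positions, in 11p15.4 and in 8q21.2, against a random mean of 0.082, with an adjusted permutation p of 0.011. That call was lost with peaks widened by 1 kb, at an adjusted permutation p of 0.26, and without second runs, where 0 were shared, and the 11p15.4 position also appears in both wild-type lists. The PC9-OR METTL7A list shared 15 peaks, 1.22%, with the parental wild-type list, against a random mean of 1.83 and an adjusted permutation p of 0.0075, and without second runs 0 were shared. Of the 15, 13 lay in the second wild-type run, 15.7% of its 83 peaks with an exact 95% interval of 8.61 to 25.3%. They include 2 peaks in 5p15.33, 2 in 5p13.1, and 1 each in 5p13.2, 11q13.3 and 16q24.3. Within the PC9-OR METTL7A list the 15 shared peaks had a median fold of 5.83 against 4.63 for the other 4920, with a two-sided permutation p of 0.0043. With peaks widened by 1 kb the difference fell to 0.592 and the permutation p was 0.11.

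A segment of 11p15.4 was called in 4 of the 6 lists. In those of the 4 that hold 2 runs, only the second run called it. It spanned 11:5246149-5247343 in PC9-OR with METTL7A, with a fold of 7.70 and 680 recovered fragments, and 11:5246136-5247344 in PC9 with METTL7A, with 15.6 and 342. In parental wild type it spanned 11:5246148-5247336, with 9.61 and 246. In PC9-OR wild type, where it was the only peak of its run, it spanned 11:5246133-5247357, with 124 and 3577. The starts differed by at most 16 bp and the ends by at most 21 bp. It was the only position in 3 or more lists, and the only one PC9-OR METTL7A shared with PC9-OR wild type, at an adjusted permutation p of 0.045. That call was lost with peaks widened by 1 kb, at 0.26, without peaks near centromere bands or off the standard chromosomes, at 0.052, and without second runs, where 0 were shared. The METTL7A list of PC9-OR shared 0 standard-chromosome peaks with the empty-vector list and 0 with K86A.

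The control lists of PC9-OR were thin apart from that segment. In the wild-type list the other 9 peaks had 3 or 4 recovered fragments and folds up to 4.92. The empty-vector list held 4 peaks on chromosome 2, in 2q14.1, 2p16.3, 2q21.3 and 2p23.1, 1 in 19q12, each with 5 or 6 fragments, and 1 on the mitochondrial genome at 9720-9953 with 81. The K86A list held 22:35832659-35832926 in 22q12.3, with a fold of 5.93 and 6 fragments. Near centromere bands, within 1 Mb, lay 2.84% of the PC9-OR METTL7A peaks against 1.95% in random placement, with a permutation p of 0.001, the smallest possible, but the first run alone did not pass, with 1.515% against 1.697% and a permutation p of 0.68. The shares in parental wild type, 1.79% against 1.53%, and in PC9 with METTL7A, 1.79% against 1.39%, did not pass, with permutation p of 0.25 and 0.54. Within 100 kb parental wild type did pass, with 0.816% against 0.154% and a permutation p of 0.001. Peaks inside the bands were counted, but random positions could not fall there. The random shares are thus too low, and the passing values do not show an excess near centromeres.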

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

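The tests in this part were chosen after their results had been seen, except that of the fold needed at raised background and that of the region around the 11p15.4 segment.

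METTL7A over wild type gave a peak number ratio of 0.0457 in PC9, where 1 METTL7A run stands against 2 wild-type runs, and 494 in PC9-OR. By peak number the directions were opposite in the lines in every run, and the difference was not tested. At a −log10 q of at least 5 the PC9 lists held 4 peaks each. A thin parental wild-type library is a candidate explanation for the PC9 side, since 92.7% of those peaks rest on at most 3 recovered fragments. All of these came from the first wild-type run. Against the second it was 56 METTL7A peaks to 83, with a METTL7A floor 0.715 times that of this run. Depth and METTL7A cannot be told apart there. Depth is argued against for the gap between the METTL7A runs of PC9-OR, since the floor of the run with 4870 peaks is 0.504 times that of the run with 67. Against the PC9-OR controls, depth and METTL7A cannot be told apart, because the lower METTL7A floor is 2.007 times the higher floor of the 2 control runs that have one, and the other 3 control runs have none. Sites called in both METTL7A runs do not make up most of the first-run peaks. Their share of these has an upper exact 95% bound of 10.5% (with peaks widened by 1 kb the share itself is 15.2%). For the whole list, runs of 67 and 4870 peaks fixed this outcome in advance. METTL7A occupancy that varies between replicates and a difference in the immunoprecipitation stay open and untested.

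Crowding at 20q13.3 and 3p25 stands out because the local background recovered in parts of these regions, a quantity outside the peak comparison, is raised, with second-run medians of 5.67 and 9.05 floors in the windows from 57 to 59 Mb of chromosome 20 but only 1.0 to 1.33 in those from 60 to 63 Mb, which are crowded as well. Windows of 1 Mb were chosen on the second run, with at least 10 peaks and a median background of at least 2 floors. The 12 first-run peaks in them had a median background of 12.8 times the floor, against 1.05 for the other 54 (one-sided permutation p of 1e-05, the smallest possible). They lay only on chromosome 20 from 57 to 59 Mb and in 3p25, where neighbours share local background, so this p does not measure replication over regions. Extra copies of the parts with raised background in PC9-OR METTL7A cells are a hypothesis. It takes the control of the first run to be input, which was not checked for that run. A lower fold needed at high background is argued against as the whole cause, since 115 peaks remained in the fullest window with a fold minimum, above the highest random count of 23. Crowding in 1 run only is argued against for chromosome 20 from 55 to 60 Mb by the shares alone. There lay 15.2% of first-run peaks (10 of 66, all from 57 to 59 Mb) against 3 of 1282 parental peaks (Fisher's exact test, two-sided p of 1e-11). For 3p25, with 3.03% (2 of 66) against 2 of 1282 (Fisher's exact p of 0.013), the peaks are too few to tell. Both tests treat neighbouring peaks as independent, and 1143 of the parental peaks come from a run with at most 4 fragments per peak. Their p-values therefore do not measure replication. From 59 to 63 Mb the first run held 0.0% of its peaks and the second 4.1%. Crowding in 1 run only stays open there because the upper exact 95% bound of the first run is 5.44%. The second parental wild-type run held 3 of its 83 peaks, 3.61%, from 62 to 63 Mb, so peaks there were also called without tagged METTL7A. METTL7A binding also stays open, as do gains in the other PC9-OR cells, whose lists have no peaks to read a background from.

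The 11p15.4 segment stands out because its recovered background is 117 times the floor in parental wild type, where no tagged protein is expressed. It was at least that high in the 3 runs that called the segment and have a floor, and reached 257 in the second PC9-OR METTL7A run. The other runs with a floor, among them the first PC9-OR METTL7A run, did not call the segment and give no value there. In the runs that called it, the raised background argues against binding of the immunoprecipitated protein alone. A background computed from the immunoprecipitated library with no control would be whole multiples of 1 step. It is argued against, as at most 88.9% of a run's raised backgrounds fell within 0.05 steps of such multiples (upper exact 95% bound 96.3%). Simulated backgrounds were built as multiples of 1 step, and all were found on it. That shows only that rounding of the deposited values does not hide the steps. Extra DNA of this short segment in the control library, taken here to be the input, is a candidate explanation of the raised background only. Such DNA could be carried-over plasmid or amplified DNA, and the explanation needs the lowest value, 117, to be high. It does not account for the calls, since the immunoprecipitated fragments exceeded that background. The folds were 7.70 to 15.6 in these 3 runs. In PC9-OR wild type the fold was 124 over a background of 27.95, with no floor to set it against. A gain of the wider region cannot be told apart from such extra DNA, as 0 other peaks lay within 1 Mb in runs with a floor. No biological explanation was tested.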

How the results depend on the processing

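Of 133 values recomputed under alternatives, 104 kept their call or stayed within 1.5 times the main count. The minimum of 5 fragments, placement within 1 Mb, the fold minimum, the comparison of runs and the test across runs were chosen after seeing the data. With a −log10 q of at least 5 the lists held 4 peaks in PC9 wild type, 4 in PC9 METTL7A, 1 in PC9-OR wild type, 1 with empty vector, 0 with K86A and 436 in PC9-OR METTL7A. With at least 5 fragments, PC9 wild type fell to 83 and PC9-OR wild type to 1. These follow from fewer peaks being admitted. Leaving out each run in turn gave 83 to 1143 peaks in PC9 wild type, 1 to 9 in PC9-OR wild type, 1 to 5 with empty vector and 67 to 4870 in PC9-OR METTL7A.

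Widening by 1 kb left 1 shared peak for PC9-OR METTL7A with PC9-OR wild type, 2 with PC9 METTL7A, and 1 each for PC9 wild type with PC9 METTL7A and with PC9-OR wild type, none past 0.05, because random sharing rose as well. Between the METTL7A runs of PC9-OR it raised the shared peaks from 2 to 10, and with placement within 1 Mb the adjusted permutation p fell from 1.0 to 0.052. Without peaks near centromere bands or off the standard chromosomes, the 1 peak shared by PC9-OR METTL7A and wild type had an adjusted permutation p of 0.052. Leaving out first or second runs gave 0 to 13 shared peaks for PC9-OR METTL7A with PC9 wild type, 0 to 2 with PC9 METTL7A, and 0 to 1 for the 4 other pairs that had passed. The most filled window of PC9 wild type held 3 to 4 peaks, and the 3 of the second run passed with a permutation p of 0.02. With peaks within 10 kb merged, the fullest window of PC9-OR METTL7A moved to chromosome 5, 1 to 1000000, with 28. At a 100 kb margin the centromere share passed in PC9 wild type, at 0.816%, and in PC9-OR wild type, at 10.0%, which is 1 peak of 10. Random positions could not fall inside a band, so passing here does not show an excess. At the 1 Mb margin it was 1.515 to 2.855% by run in PC9-OR METTL7A, and the first run alone did not pass. The fold difference of shared peaks fell to 0.592 with widening and no longer passed. In PC9 wild type it was 2.82 over both runs and 0.0 in the second run alone, so it came from the difference between runs. Where not stated, the cause was not tested.

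No paired analysis was possible because the lists carry no value per replicate at positions that were not called. The promoter windows of 1 and 3 kb, coding-gene and CpG-rich backgrounds, random promoter placement and the replicate block were not run, nor was any result with no peaks left. Lists of at most 10 peaks limit what sharing can be detected, and the floor of a run limits which folds pass its threshold.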

Other observations

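Raised local background in the second PC9-OR METTL7A run was not limited to 20q13.3 and 3p25. It covered 12 windows of 1 Mb with 458 peaks, 9.41% of that run. Besides chromosomes 20 and 3 these were 4 windows of chromosome 19 between 54 and 59 Mb, at 2.53 to 3.86 times the floor, chromosome 11 from 67 to 68 Mb, at 2.15 times, and chromosome 22 from 21 to 22 Mb, at 2.91 times. The first run had 18.2% of its peaks in the 12 windows, all on chromosome 3 and on chromosome 20 from 57 to 59 Mb. It held 0 in the windows of chromosomes 19, 11 and 22, so raised background there rests on the second run alone. The parental wild-type list had 0.163%, with most of its peaks from a run of at most 4 fragments per peak. Second-run peaks inside them had a median fold of 5.07 against 4.59 outside, and a median of 12 fragments against 6. Outside the windows 64.3% of second-run peaks lay at the floor.

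With peaks within 10 kb merged, chromosome 20 from 58 to 59 Mb held 24 second-run groups of peaks in place of 144 peaks. The mitochondrial peak of the empty-vector list overlapped a mitochondrial peak of the PC9-OR METTL7A list, and each run of that METTL7A list held 1 mitochondrial peak. The second run of parental wild type, in which no tagged protein is expressed, shared 13 peaks with the second PC9-OR METTL7A run, against a mean of 0.846 when placed within 1 Mb of each peak, with a permutation p of 0.001, the smallest possible, and 0.022 after adjustment over 45 pairs of runs.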
